A study of Mus musculus with 8 samples.

How the data were processed

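The series holds 8 mouse samples of 10x single-cell RNA: mTBLC culture, blastoid, teratoma, placenta with yolk sac, and 2D differentiation at 4, 24, 48 and 96 h, with 1 library each. The deposited tables hold UMI counts of genes by cells, and the values are whole numbers, so their unit is count, as the authors deposited them. Each table came with a deposited annotation of every cell, used as given, including the spelling Immnue cells. Per the submitters' processing notes, reads were counted with Cell Ranger against mm10 and cells were filtered and annotated with Seurat; versions were not given in the sources used here. There were 5 tables: 1 each for the mTBLC culture, blastoid, teratoma and placenta with yolk sac, and 1 that pools the mTBLC cells with those of 2D differentiation. In the pooled table, 40489 columns of per-sample values were matched to no sample: their barcodes carry suffixes that no label ties to a time point. These cells were described by annotated type and by suffix, and the planned comparison of 96 h with 4 h was left out.

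Depth was 141354859 UMIs over 21231 genes in the mTBLC table (at least 10009 UMIs per cell), 567959780 over 23999 in the pooled table, 6618985 over 33502 in the blastoid table, 81272018 over 31055 in the teratoma table and 54596825 over 16327 in the placenta and yolk sac table. A count of 0 was read as allowing up to 3 counts. Median mitochondrial shares were 10.0% in the mTBLC, 4.17% in the pooled, 6.26% in the blastoid, 3.71% in the teratoma and 0.307% in the placenta and yolk sac table. No cell was removed in the values reported.

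Counts were summed over the cells of a library or of 1 annotated type and given as counts per 1000000 UMIs (CPM) with exact Poisson intervals. Shares have Clopper-Pearson intervals and ratios of 2 counts exact conditional binomial intervals. Log2 ratios used CPM + 1. Genes were compared between libraries only if both tables hold them: 21231 for blastoid and mTBLC culture, where the 12271 genes left out hold 0.0134% of blastoid UMIs, and 19957 for teratoma, where 11098 genes left out hold 0.0714%. Before the data were examined, 39 lists with 447 genes were fixed, as were the comparisons, the naming rule and most alternatives. Of the list genes, 405 were found in the mTBLC table, 424 in the pooled, 445 in the blastoid, 445 in the teratoma and 363 in the placenta and yolk sac table. A member counted as measured from 5 CPM in at least 1 side and as higher or lower from a 2-fold difference. A list median was called apart from random lists outside percentiles 2.5 to 97.5 of 10000 random lists matched on expression in 20 bins, with at least 3 measured members. All list medians by type in the text were so called except where said. A member that reaches 5 CPM only in the type described can only lie higher there, so counts of higher members by type are partly fixed. The types were annotated on these same cells, so list values by type describe the annotation and do not test it. Counting intervals of list medians came from 1000 Poisson redraws. Genes named by size were the 12 highest and 12 lowest log2 ratios at 50 CPM or more in the higher library, without Gm, Rik, mitochondrial and ribosomal protein symbols, and for each type of at least 50 cells the 5 highest against all other cells. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs, and for eGFP in placenta and yolk sac to 1000 UMIs outside haemoglobin genes.

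The mTBLC, pooled and blastoid tables use other gene symbols than the teratoma and the placenta and yolk sac tables. A symbol from 20 CPM was taken as split between the tables when it had 0 counts in the first 3 tables (72 symbols) or at most 10% of its level in the last 2 (72). Of the symbols with 0 counts, 53 are older names of a current symbol in the RefSeq table, and 52 of these genes were counted under it in the mTBLC table, such as Fam60a under Sinhcaf. The rule uses levels alone, so for the other symbols the cause was not tested. This rule, the split of cells by eGFP, the Y-linked and Xist counts, the comparisons of single types and the thinning outside haemoglobin were added after the data were seen. Alternatives were totals without mitochondrial, ribosomal protein and haemoglobin genes, the mean of per-cell CPM, a pseudocount of 5 CPM, members from 20 CPM, only cells with at least 1000 genes and at most 10% mitochondrial UMIs, TMM factors, and removal of doublets. Scrublet's automatic threshold called 2 of 4882 mTBLC cells, 9 of 300 blastoid cells, 1 of 3471 teratoma cells and 0 of 3984 placenta and yolk sac cells, too few to count as working, so removal of the 5% of cells with the highest scores was added. The calculation was tested on simulated data of the depth of the libraries. Both simulated libraries were drawn from the mTBLC profile with few genes changed. Of 400 unchanged lists, 3.00% were called in the blastoid and 4.50% in the teratoma comparison. Of 200 lists made 2-fold different, 100% were called in both. Poisson intervals held the true mean in 95.5% and 95.3% of genes. The real libraries differ in many genes, so the rates of calls do not give those of the real comparisons. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 with its Scrublet, scikit-learn 1.9.0, matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3.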

Results

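Single-cell transcriptomes were examined from 8 mouse samples whose records all name the TC1-GFP line: mTBLCs cultured in 2MYCP medium, blastoids, a teratoma, placenta with yolk sac, and 2D differentiation at 4, 24, 48 and 96 h. The mTBLC culture gave 4882 cells (median 26743 UMIs), the pool of mTBLCs and 2D differentiation 45371 (9771), blastoids 300 (19960), the teratoma 3471 (23075) and placenta and yolk sac 3984 (7049). Haemoglobin genes took 67.4% of all UMIs in placenta and yolk sac. Each group had 1 library, so there were no replicates and no difference was tested. All 95% intervals cover counting error only.

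Of the mTBLC culture, 4465 cells, 91.5% (90.6 to 92.2), carried the type mTBLC-2MYCP, 326 (6.68%) the type XEN-like cells, 68 (1.39%) feeder cells and 23 (0.471%) TBLCs. The few TBLCs held the genes of the early embryo at the highest level: 33 of 33 measured members of the totipotency and 2-cell genes were higher than in all other cells (median log2 ratio 3.64). For mTBLC-2MYCP only 15 members were measured. Members that reached 5 CPM in TBLCs alone could only lie higher there, so the count is partly fixed by the rule. Tcstv3 stood at 1161 (95% interval 1082 to 1243) counts per 1000000 UMIs (CPM) in TBLCs and 12.6 in mTBLC-2MYCP. Zfp352, a zinc-finger gene switched on at the 2-cell stage, stood at 208 and 2.31. Zscan4c and Zscan4d, of a gene family active in telomere maintenance and at the 2-cell stage, stood at 662 and 668 CPM in TBLCs against 46.3 and 57.9. The split of reads between these near-identical copies is uncertain. XEN-like cells held all 15 measured primitive endoderm genes at a higher level (median 4.73), with the transcription factors Gata6 at 360.4 and Sox17 at 117 CPM. Of 10 measured genes of trophectoderm and trophoblast stem cells, 6 were higher in them and 1 lower (median 1.82). The totipotency list (median -2.26) and naive pluripotency (-1.12) were lower in them. The leading genes of mTBLC-2MYCP were Fgf4 (65.1 CPM against 6.67 in all other cells), Igfbp2, Nanog, Tdh and Ifitm1. In this type 9 of 16 measured genes of naive pluripotency, the state of the unimplanted epiblast, were higher (median 1.33). Feeder cells were set apart by smooth muscle genes (4 of 4, median 5.67) and by those of mesenchyme and fibroblasts (10 of 11, median 3.92).

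With each cell thinned to 2000 UMIs, Zscan4c was seen in 39.1% of TBLCs (19.7 to 61.5), 3.78% of mTBLC-2MYCP and 2.94% of feeder cells, a type that should lack it. Without thinning the shares were 82.6%, 13.8% and 8.82% at median depths of 25623, 26262 and 35390 UMIs, and 0 cells were too shallow to thin. Gata6 was seen in 50.6% of XEN-like cells, 0.941% of mTBLC-2MYCP and 2.94% of feeder cells after thinning, and in 92.3%, 8.60% and 13.2% without it. The thinned share of Gata6 in mTBLC-2MYCP lay within the interval of the feeder cells (0.358 to 10.2%). That interval, the same for Zscan4c, rests on 2 of 68 feeder cells, so it is too wide to set a level of background. In summed counts Zscan4c stood at 2.47 (95% interval 0.906 to 5.38) CPM in feeder cells against 46.3 in mTBLC-2MYCP.

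The pooled table carried 10 deposited types, among them several named after stages of the early embryo. The type zscan4 (2596 cells, 5.72%) held 30 of 30 measured genes of the totipotency list at a higher level than all other cells (median 5.05). It was led by Zscan4d at 451 (95% interval 444 to 459) and Zscan4c at 273 CPM, with the same doubt on near-identical copies. In post-epi (4533 cells) the genes of formative and primed pluripotency, typical of the implanting epiblast, were higher (9 of 12, median 3.24) and those of naive pluripotency lower (12 of 16, median -2.03). The de novo DNA methyltransferase gene Dnmt3b stood at 1348 CPM in post-epi and 26.2 in minor-zga, Fgf5 at 64.7 and 0.163, and the pluripotency factor Klf4 at 7.36 and 178. Pou5f1, which encodes OCT4, stood at 705 CPM in cell4, 711 in cell8_16_morula and 128 in minor-zga. The type epi had 9 of 11 measured formative and primed pluripotency genes higher (median 1.42). The type xen led with genes of primitive endoderm (16 of 16, median 4.29) and visceral endoderm (10 of 13, median 4.19), including the endocytosis genes Dab2 (2289.7 CPM) and Cubn (1016). Feeder cells led with smooth muscle genes (median 5.81) and mesenchyme and fibroblasts (4.63).

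The type named TE (1359 cells), by its name trophectoderm, had higher primitive endoderm genes (16 of 16, median 3.25) and parietal endoderm genes (8 of 11, median 2.35). In it Gata6 stood at 310.0, Sox17 at 89.2 and Srgn at 670.4 CPM, the keratin gene Krt8 at 417, and the trophectoderm factors Cdx2 and Elf5 at 2.49 and 0.583. The mTBLC cells stood in this table too, with identical counts and a second annotation: 268 of the 326 cells named XEN-like in the mTBLC table were named TE here. Of the 23 TBLCs, 20 were named zscan4. Of the 4465 mTBLC-2MYCP cells, 4064 were named minor-zga and 316 zscan4. Without the mTBLC library, the TE type kept its primitive endoderm genes (median 3.04) and had 7 of 13 measured genes of trophectoderm and trophoblast stem cells higher (median 1.06).

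By the naming rule, the leading genes were Cited4, Mov10l1, Rhox6, Mapt and Itpk1 in cell4, Cdkn1c, Rasgrp2, Pla2g10, Dusp9 and Hsd17b14 in cell8_16_morula, Dio3, Aspa, Fgfbp1, Ly6c1 and Ly6a in major_zga. They were Cdx1, Snhg3, Rpa3, Snhg6 and Snhg8 in minor-zga, Klf12, Lef1, AY036118, Pdzd4 and Lars2 in epi and Pim2, Pou3f1, Lef1, Fgf5 and Bcl11a in post-epi. The type minor-zga drew 97.8% of its cells from the mTBLC library. Its 91 cells from the other 4 libraries, set against the other cells of these, had a formative and primed pluripotency median of -0.44 and one of naive pluripotency of 0.02, not apart from random lists, where all minor-zga cells had -2.54 and 0.23. The 40489 cells outside the mTBLC library came from 4 libraries whose time points the tables do not name, so no value was assigned to 4, 24, 48 or 96 h. Zscan4d was seen in 28.0% of zscan4 cells thinned to 2000 UMIs (66 shallower cells left out) and in 0.319% of feeder cells (114 left out), which should lack it. Without thinning the shares were 44.2% and 1.49% at median depths of 9648.5 and 14343 UMIs.

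**Figure D1:**
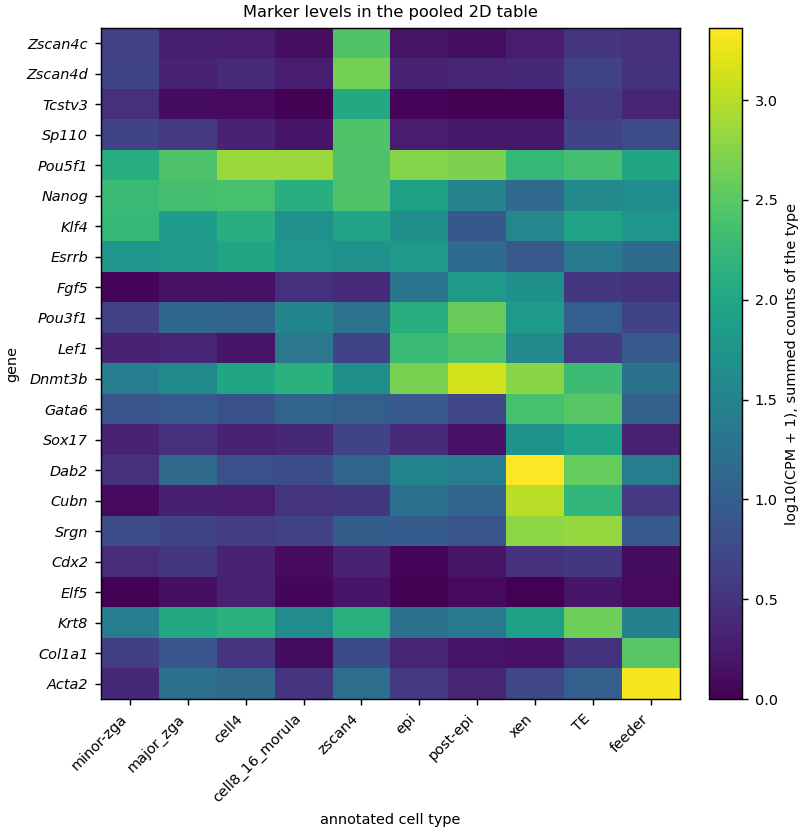
Level of 22 marker genes (vertical axis) in the 10 deposited types of the pooled table (horizontal axis), as log10(CPM + 1) of summed counts, without error bars. Zscan4d reached 451 CPM in zscan4, Dnmt3b 1348 in post-epi and Gata6 310.0 in TE.

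The blastoid table held exactly 100 cells of each of 3 types. As a description of the annotation, ICM/EPI, PrE and TE differed in the gene programmes of the 3 blastocyst lineages. ICM/EPI had higher naive pluripotency genes (12 of 15, median 3.57) and higher totipotency and 2-cell genes (6 of 6, median 3.43). In it stood the pluripotency factors Nanog at 70.9 (95% interval 61.5 to 81.3), Pou5f1 at 71.6 and Sox2 at 85.1 CPM. PrE had higher primitive endoderm (16 of 16, median 4.48), visceral endoderm (8 of 8, 4.44) and parietal endoderm genes (10 of 10, 4.06). In PrE stood the endoderm factors Sox17 at 323 (95% interval 297 to 351), Gata4 at 185 and Gata6 at 95.9 CPM and the basement membrane collagen gene Col4a1 at 4086. TE had higher genes of trophectoderm and trophoblast stem cells (16 of 18, median 3.64) and of spongiotrophoblast and glycogen cells (3 of 3, 5.05). Its keratin genes Krt8 and Krt18 stood at 2056 (95% interval 1993 to 2120.0) and 1923 CPM, the placental gene Plac1 at 247 and the imprinted placental growth regulator Phlda2 at 2445. Cdx2, a factor of early trophectoderm, stood at 9.06 (95% interval 5.37 to 14.3) CPM in TE, 20.1 (95% interval 14.0 to 28.0) in PrE and 10.0 (95% interval 6.72 to 14.4) in ICM/EPI, so it was not higher in TE. Leading genes were Tdgf1, Trh, Nanog, Pla2g1b and Dppa3 in ICM/EPI, Pitx1, Srgn, Spink1, Cubn and Igfbp1 in PrE and Rhox9, Anxa1, Nrk, Krt7 and Plac1 in TE. Median depths were 31551, 7875 and 16362 UMIs.

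**Figure D2:**
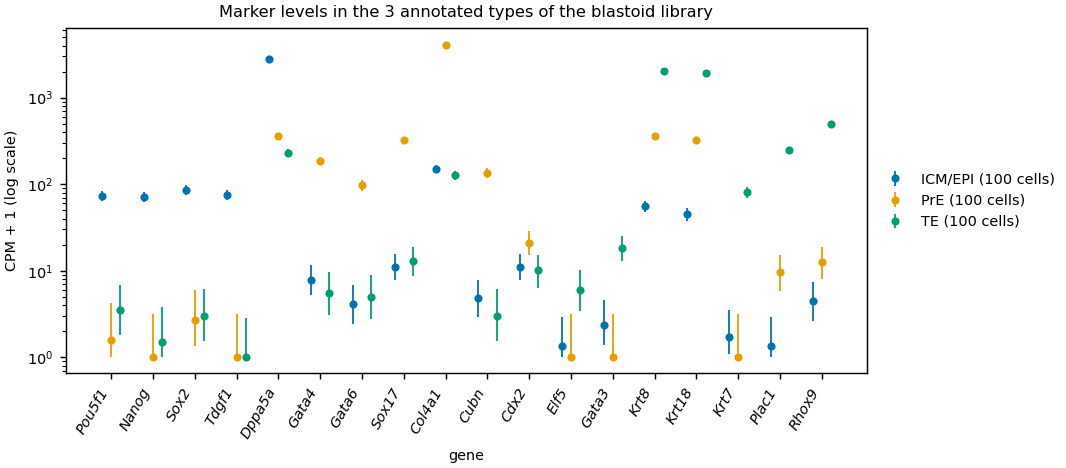
CPM + 1 of 18 genes (vertical axis, log scale) in ICM/EPI, PrE and TE cells of the blastoid table, with exact Poisson 95% intervals as error bars. Plac1 stood at 247 CPM in TE and Sox17 at 323 in PrE.

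Over all cells, the blastoid library held more transcript of trophoblast and extraembryonic endoderm genes, and less of totipotency and naive pluripotency genes, than the mTBLC culture. Of 18 measured genes of trophectoderm and trophoblast stem cells, 16 were at least 2-fold higher and 1 lower, with a median log2 ratio of 3.81 (counting interval 3.62 to 3.96). Krt8 stood at 736 against 42.7 CPM, Plac1 at 76.6 against 0.0283 (2707-fold, 1051 to 9973). The trophoblast factors Gata2 and Cdx2 stood at 56.8 against 0.318 and 12.4 against 1.53, while Eomes was lower, at 3.32 against 11.3. Of 16 measured primitive endoderm genes, 15 were higher (median 2.60, counting interval 2.51 to 2.69). Sox17 stood at 92.9 against 11.1 CPM (8.39-fold, 7.63 to 9.21) and Gata4 at 53.03 against 7.62, whereas Gata6 stood at 27.8 against 35.7. The lists of visceral endoderm (6 higher and 2 lower of 10, median 3.48) and parietal endoderm (8 of 11 higher, median 2.19) were higher too. All 13 measured totipotency genes were lower, with a median of -2.92 (counting interval -3.22 to -2.58). Zscan4c stood at 2.42 against 45.1 CPM, Zscan4d at 1.96 against 55.7 (28.4-fold lower, 16.6 to 53.3) and Gm8300 at 33.7 against 164. Tcstv3 had 0 counts against 17.6 CPM. Of the naive pluripotency genes, 15 of 16 were lower (median -2.25, counting interval -2.37 to -2.21), such as Nanog (31.1 against 187 CPM), Pou5f1 (32.2 against 117) and Esrrb (4.53 against 52.8). Dppa3, a maternal-effect and germ-cell gene, was the 1 higher member, at 59.4 against 4.05.

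Imprinted genes were higher as a list (8 of 13, median 1.63). H19 stood at 1062 against 3.16 CPM (337-fold, 306 to 371) and Igf2, a fetal growth factor gene, at 143 against 0.248. Peg10, needed for the placenta, stood at 1241 against 14.6, and Cdkn1c, a cell cycle inhibitor gene, at 340.2 against 4.93, while Plagl1 was lower, at 4.53 against 43.5. The formative and primed pluripotency list was higher in 5 of 8 genes (median 1.71), with Tdgf1 lower at 32.6 against 348. Other higher medians apart from matched random lists were those of spongiotrophoblast and glycogen cells (4.41), syncytiotrophoblast and labyrinth (2.14), gut and airway epithelium (2.31), mesoderm and primitive streak (1.98), squamous epithelium (1.22) and polarity and Hippo (0.91). Lower ones were those of neural progenitors and neurons (-2.25) and skeletal muscle (-1.31), the last with 3 measured members. By size, the naming rule gave H19, Spink1 (301 against 0.608), Igf2, Nrk (191 against 0.969), Peg10, Plac1, Cdkn1c, Krt18, Gata2, the tight junction gene Cldn7 (173 against 3.39), Pth1r (194 against 3.94) and S100g (609.9 against 17.5) as higher in the blastoid library. It gave as lower Ly6a, the gene of the surface antigen Sca-1 (1.21 against 235 CPM, 195-fold lower, 98.7 to 451), the maternal-effect gene Khdc3 (0.755 against 163), Crxos (0.604 against 115), the germ-cell RNA-binding gene Dazl (1.81 against 154), Krt42, Cdx1 (1.21 against 54.5), Sept1 (11.2 against 299), Fam25c, Zscan4d, Jam2, Laptm5 and Zfhx2.

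The medians of the 2 lower embryo lists lay below, and those of the 3 endoderm lists, trophectoderm and trophoblast stem cells, imprinted genes, formative and primed pluripotency, spongiotrophoblast and glycogen cells and gut and airway epithelium above, all 10000 random lists matched on expression, as a description of these libraries. The level over all blastoid cells depends on the equal number of cells per type: between ICM/EPI cells and mTBLC-2MYCP cells alone, the median of trophectoderm and trophoblast stem cells was 1.76 and that of totipotency and 2-cell genes -1.97, and the log2 ratio of Plac1 was 0.39 in place of 6.24. Between those cells the lists of squamous epithelium, skeletal muscle and gut and airway epithelium were not apart from random lists. Squamous epithelium was not apart with the mean of per-cell CPM either (percentile 94.7). Over all cells, formative and primed pluripotency was not apart with members counted from 20 CPM (median 0.67, percentile 91.1).

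**Figure D3:**
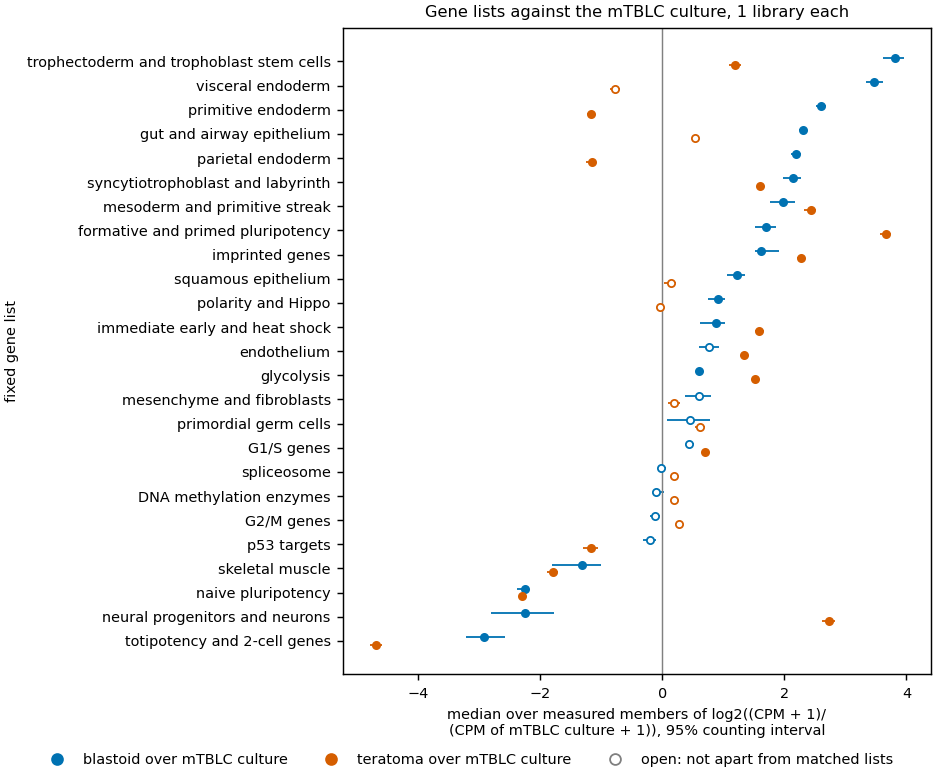
Median log2 ratio (horizontal axis) of 25 gene lists (vertical axis) in the blastoid and the teratoma library over the mTBLC culture, with counting intervals as error bars and open symbols for medians not apart from matched random lists. The totipotency median was -2.92 in the blastoid and -4.69 in the teratoma library.

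The teratoma library held more transcript of post-implantation epiblast, neural, glial and primitive streak genes than the mTBLC culture, and less of totipotency and naive pluripotency genes. In the list of formative and primed pluripotency, 10 of 12 genes were higher (median 3.66, counting interval 3.57 to 3.75). Examples were Fgf5 at 29.3 against 0.191 CPM, the head and epiblast factor Otx2 at 158 against 4.63, Pou3f1 at 96.6 against 3.66 and Dnmt3b at 283 against 27.8. Tdgf1, a Nodal co-receptor gene, was lower at 115 against 348. Among neural progenitors and neurons, 8 of 11 genes were higher (median 2.73, counting interval 2.62 to 2.84), such as the neural transcription factors Sox11 (524 against 7.92 CPM), Ascl1 (24.9 against 0.0778) and Pax6 (12.6 against 0.233). Stmn2 was lower (105 against 411). All 3 measured genes of glia were higher (median 2.67). Fabp7 of radial glia stood at 69.3 against 0.0920 CPM and the myelin genes Plp1 and Mbp at 16.7 against 1.78 and 15.4 against 2.82. So were all 3 of cartilage (median 3.85), with the collagen gene Col2a1 at 35.4 against 1.52 and Sox9 at 28.3 against 0.757. No type bore a cartilage name, and the list was higher in neural types, such as Retinal ganglion cell (2.61), Dopamine neural precursors (1.95) and Gliogenic precursors (1.32). Of mesoderm and primitive streak, 3 of 4 genes were higher (median 2.43), with Fgf8 at 49.7 against 0.368 and T, which encodes Brachyury, at 18.2 against 2.66. All 13 measured totipotency genes were lower (median -4.69, counting interval -4.79 to -4.59). Zscan4d had 0 counts against 55.7 CPM, at least 1227-fold lower by the 95% interval. Of the naive pluripotency genes, 14 of 16 were lower (median -2.30, counting interval -2.34 to -2.25), with Klf4 at 24.3 against 168 CPM, Zfp42 at 94.3 against 720.2 and Nanog at 73.7 against 187. Dppa3 was higher at 49.5 against 4.05, and Sox2, shared with neural cells, stood at 295 against 285. Of trophectoderm and trophoblast stem cells, 5 of 9 measured genes were higher and 1 lower (median 1.19, counting interval 1.10 to 1.28, percentile 99.6). Fgfr2 stood at 36.6 against 2.98, Id2 at 86.1 against 11.0 and Krt18 at 43.5 against 13.7, but Krt8 at 30.8 against 42.7. Over all teratoma cells Cdx2 stood at 0.554 CPM and Elf5 at 0.0369.

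Of the lists of extraembryonic endoderm, primitive endoderm (9 lower and 1 higher of 12, median -1.16) and parietal endoderm (8 and 2 of 11, median -1.15) were lower. The mTBLC culture held 6.68% of XEN-like cells and 1.39% of feeder cells. When immune cells and fibroblasts were left out of the teratoma and mTBLC-2MYCP alone was the reference, these 2 medians turned to 0.93 and 0.50 and were not apart from matched lists. The medians of syncytiotrophoblast and labyrinth (1.60) and endothelium (1.34) were higher, with 4 measured genes each, and that of skeletal muscle was lower (-1.80). The medians of visceral endoderm (-0.77) and mesenchyme and fibroblasts (0.19) were not apart from random lists, and their sign depended on the setting. Over the alternatives they ran from -0.99 to 2.59 and from -0.81 to 1.85. Under 2 of them, the pseudocount of 5 CPM (-0.55) and the cell filter (-0.99), visceral endoderm was apart from random lists, as lower. Those of the formative and neural lists lay above, and those of totipotency, naive pluripotency, primitive endoderm and parietal endoderm below, all 10000 random lists; the percentiles of glia, cartilage and mesoderm and primitive streak were 98.5, 99.5 and 98.8. The trophoblast median lost this standing (percentile 95.8) when members were counted from 20 CPM. Endothelium lost it under 4 alternatives: members from 20 CPM (percentile 56.8), the mean of per-cell CPM (95.4), the cell filter (97.4) and totals without mitochondrial, ribosomal protein and haemoglobin genes (58.4, median 0.21).

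Of the 24 genes named by size between teratoma and mTBLC culture, 10 of the 12 higher and 6 of the 12 lower met a rule, added after the values were seen, for symbols counted almost only in the tables of 1 side. Of these higher symbols 9, such as Fam60a, have a current symbol under which the mTBLC table counts the gene, so their 0 counts there reflect the symbol in use. The levels under the 2 symbols could still differ. In the teratoma and the mTBLC culture they stood at 328 and 65.5 CPM for Fam60a and 143 and 60.8 for Zcchc11. Those of Sssca1 were 126 and 125, and those of Aes 77.2 and 184. The 6 symbols among the lower genes are counted in the mTBLC table, so this search could not apply to them. Older symbols for them in the teratoma table were not looked for. Atp5o stood at 0 against 471 CPM and Atp5o.1 at 364 against 0, as for 1 gene counted under 2 symbols. Why the other lower ones differ was not tested. These were Atp5o.1, Fam60a (328 against 0 CPM), Usmg5, Minos1, Zcchc11, Sssca1, Fam96a, Fam96b, Mgea5 and Aes among the higher, and Atp5o, Atp6v0c, Rnasek, Mrpl53, Aarsd1 and Nme2 among the lower. With all symbols that met the rule left out, the higher genes were Nnat, an imprinted gene of the developing brain (378 against 0.559 CPM, 676-fold, 542 to 854), Ptn (131 against 0.460), Igfbp5 (98.9 against 0.297), Ptp4a1 (134 against 1.05), Fabp7 and Hsd11b2 (77.1 against 0.262). They also held the morphogen gene Shh (62.1 against 0.0637), Sox11, the forebrain and eye factor Six3 (55.3 against 0.177), Pitx2, the floor plate and endoderm factor Foxa2 (86.1 against 1.61) and Crabp2, of retinoic acid binding (101 against 2.25). The lower genes were Ly6a (1.08 against 235 CPM, 217-fold lower, 176 to 271), Zscan4d, Myl4, Khdc3 (3.77 against 163), Crxos, Cdx1, Laptm5, Gpx2, Tomm6, Mylpf (17.7 against 341), Triml1 and Krt42. A total of 144 symbols met the rule, 2 of them in a fixed list (Gm8300 and Hbb-bs). The rule looks at levels alone, so it also takes genes whose level differs between the libraries. Without Gm8300 the totipotency median was -4.45. For a symbol of the mTBLC side, the rule asks for 20 CPM in each mTBLC, 2D and blastoid library. Zscan4d, Zscan4c and Tcstv3 stood under that in the blastoid library, so the rule could not take them. The median without Gm8300 therefore does not test whether the symbols in use account for the low totipotency genes.

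The deposited annotation divided the teratoma into 15 types. The largest was Epiblast, with 675 of 3471 cells, 19.4% (18.1 to 20.8). ICM followed with 16.5%, Neuroepithelium with 13.5%, Radial glia cells with 10.5%, Gliogenic precursors with 9.25%, Retinal ganglion cell with 6.396%, Trophoblast progenitors with 5.36%, Dopamine neural precursors with 5.07% and Interneurons with 3.95%. Primitive endoderm held 2.82%, Early neurons 2.65%, Primitive streak 1.64%, Immnue cells 1.61%, Oligodendroglia 0.864% and Fibroblasts 0.432%. Epiblast led with Pim2 (387 CPM against 57.4 in all other cells), Fgf5, Dnmt3b (759 against 134), Cldn7 and Zic5. ICM led with Mymx, Nr0b1, Spp1, Hspb1 and Dppa2, where 12 of 15 naive pluripotency genes were higher (median 2.35). The neuronal types Interneurons and Early neurons held more transcript of neural progenitors and neurons (9 of 12, median 2.60, and 11 of 12, median 2.68), with the neuronal tubulin gene Tubb3 at 685 and 684 CPM. Primitive endoderm led with S100g, Cym, Igfbp1, Ttr and Cubn, with 11 of 11 visceral endoderm genes higher (median 5.27). Primitive streak led with Cer1, Lhx1, Mixl1, Sox17 and Bmp2, with 6 of 6 genes of its list higher (median 2.995) and T at 299.7 CPM. Immnue cells led with Lyz2, Cd74, H2-Aa, Cxcl2 and Fcer1g and had all 12 measured macrophage and myeloid genes higher (median 8.36).

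The type Trophoblast progenitors led with the X-linked homeobox genes Rhox9 (254 CPM) and Rhox6 (232), of a family of near copies, and with Dppa3 (541 (95% interval 521 to 561)), Tfap2c (126) and Tex14. In it all 6 measured genes of primordial germ cells were higher (median 3.23), with Dazl at 459.6 (95% interval 441 to 478) CPM. The trophoblast genes Cdx2, Krt8 and Plac1 stood at 2.29, 2.87 and 0.382 CPM and Gata3 and Elf5 had 0 counts. Among the other neural types, leading genes were Vstm2b, Foxb1, Cyp26a1, Hsd11b2 and Tgfb2 in Neuroepithelium, Crabp1, Nkx6-2, Ednrb, Hoxb3os and Fam181b in Radial glia cells. They were Dbx1, Maf, Fezf2, Lhx2 and Six3 in Gliogenic precursors, Dlk1, Nfix, Mt3, Fabp7 and Nfia in Retinal ganglion cell and Dmrta2, Dkk2, Lmx1a, Wnt1 and Samd5 in Dopamine neural precursors. The last include Lmx1a and Wnt1, of the midbrain floor. In Retinal ganglion cell the genes of glia (2.35) and of neural progenitors and neurons (1.83) both had higher medians. Interneurons led with Dlx6os1, Syt1, Chgb, Nrxn3 and Calb1, and Early neurons with Neurod4, Ebf2, Neurog1, Nhlh1 and Phox2b. Of 2 types under 50 cells, described on lists alone, Oligodendroglia had higher glia genes (8 of 8, median 6.33, with Mbp at 643 CPM). Fibroblasts had higher genes of mesenchyme and fibroblasts (12 of 12, median 5.23) as well as of endothelium (11 of 11, median 3.76, with Kdr at 165).

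**Figure D4:**
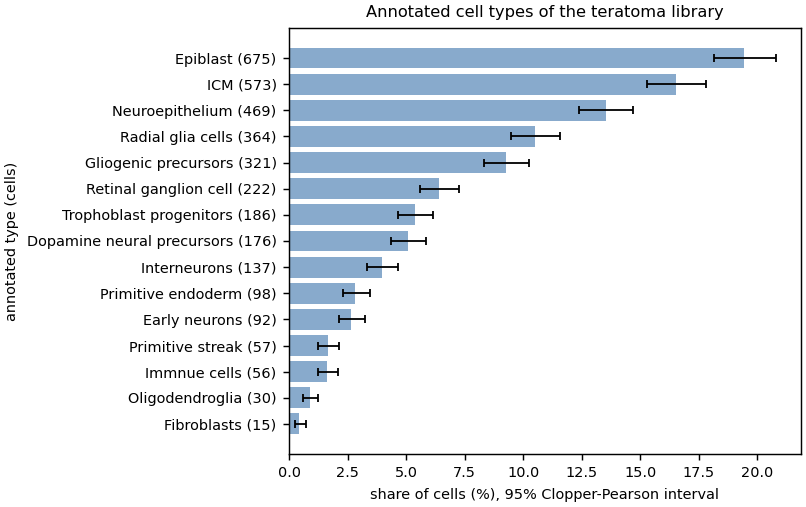
Share of teratoma cells in percent (horizontal axis) in each of the 15 deposited types (vertical axis), with exact Clopper-Pearson 95% intervals as error bars. Epiblast held 19.4% and Fibroblasts 0.432%.

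Transcript of the eGFP marker of the line, counted as eGFP-F and eGFP-R, was seen across the teratoma, at 150.1 and 53.9 CPM over all cells. No type was named beforehand as lacking eGFP, so no level of background was set. With cells thinned to 2000 UMIs, 31.0% of all cells held an eGFP UMI (48 shallower cells left out), 37.8% of Epiblast cells (5 left out), 12.9% of Interneurons (5) and 8 of 40 Immnue cells (9.05 to 35.6; 16 of 56 left out). Unthinned, the shares were 87.5%, 97.0%, 40.9% and 30.4% at median depths of 23075, 30281, 7552 and 3134 UMIs. Xist, the RNA that silences 1 X chromosome in female cells, stood at 3.49 CPM over all cells, 162 in Immnue cells and 113 in Fibroblasts, where 11 of 56 and 2 of 15 cells held a Xist UMI. Within Immnue cells it stood at 312 per 1000000 UMIs outside haemoglobin genes in the 39 cells without an eGFP UMI. In the 17 cells with one it stood at 41.6 (ratio 0.133, 0.0506 to 0.300). Xist UMIs lay in only 8 of those 39 and 3 of those 17 cells, and the interval takes UMIs as independent. Y-linked genes stood at 42.7 CPM over all cells and 16.5 (5.36 to 38.5) in Immnue cells.

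Blood cells made up most of the placenta and yolk sac library. Neutrophils held 988 of 3984 cells, 24.8% (23.5 to 26.2), Primitive RBCs 24.4%, Definitive RBCs 16.7% and erythroid precursor cell 6.38%. These shares depended on the cells kept: with at least 1000 genes and at most 10% mitochondrial UMIs they were 38.0%, 17.9%, 0.357% (6 cells) and 14.5%. SpA-TGC held 7.86%, Yolk sac cells 4.74%, Macrophage 3.71%, Decidual stroma 3.29%, S-TGC 3.06%, SynTII 2.31%, SynTI 1.38%, Visceral yolk sac 0.879% and Gly-T 0.502%. Primitive RBCs carried mostly embryonic β-globin, with Hbb-y at 371866 CPM against 47375 for the adult Hbb-bs. Of their α-globin UMIs, only 27.8% were of the embryonic Hba-x, at 97290.5 CPM, and the rest of the adult genes. Definitive RBCs carried mostly adult β-globin, with Hbb-bs at 364652 and Hbb-bt at 180346 against 4413 for Hbb-y. The split of reads between Hbb-bs and Hbb-bt, close copies, is uncertain. The precursors held Hbb-y at 282738 CPM, the erythroid factor Klf1 at 60.6 and the proliferation gene Mki67 at 462. Neutrophils had all 6 measured granulocyte genes higher (median 7.37), with S100a8 at 24937 CPM. Macrophage had 11 of 12 macrophage and myeloid genes higher (median 4.44), with the complement gene C1qa at 1217. Yolk sac cells had all 14 measured visceral endoderm genes higher (median 6.95), with alpha-fetoprotein (Afp) at 45245 and the apolipoprotein gene Apob at 2775 CPM, and so had Visceral yolk sac (14 of 14, median 5.91).

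The types with trophoblast names differed in the genes they held. SpA-TGC had higher genes of trophoblast giant cells (10 of 10, median 5.17) and of spongiotrophoblast and glycogen cells (10 of 10, 4.74), with Tpbpa at 6399.9 CPM and the placental lactogen gene Prl3b1 at 913 (1876 as the mean of per-cell CPM). It also had higher genes of mesenchyme and fibroblasts (9 of 9, 7.68) and of maternal decidua (7 of 8, 5.69), with Col1a1 at 1821 and Prl8a2 at 2535. SynTI had all 9 measured squamous epithelium genes higher (median 6.403), with the keratin genes Krt8 at 3286 and Krt5 at 2095 CPM (1206 as the mean of per-cell CPM). It had 0 counts of Syna and Synb, the fusion genes of the syncytium. Yet the summed level of the syncytiotrophoblast and labyrinth list was highest in SynTI among all types, at 863 CPM (819 to 908). SynTII had all measured lymphoid (9 of 9, median 5.12) and macrophage and myeloid genes (12 of 12, 4.16) higher. Its antigen presentation genes Cd74 and H2-Aa stood at 2907 and 1073 CPM, against Krt8 at 3.61 and a syncytiotrophoblast and labyrinth median of -0.86. In Gly-T, under 50 cells and described by genes chosen after the values were seen, the mast cell and basophil genes Mcpt8, Ms4a2 and Cpa3 stood at 1806, 1309 and 811 CPM and Tpbpa at 54.1. Decidual stroma held the granzyme gene Gzmd at 535 CPM (1275 as the mean of per-cell CPM) and Hbb-y at 296200, and S-TGC the muscle actin gene Acta1 at 685 and Krt8 at 1160.1.

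eGFP transcript in placenta and yolk sac was found in erythroid precursors and Primitive RBCs and hardly in Definitive RBCs. Per 1000000 UMIs outside haemoglobin genes, eGFP stood at 57.3 (48.8 to 66.9) in erythroid precursors, 37.9 (32.4 to 44.2) in Primitive RBCs and 2.72 (0.560 to 7.94) in Definitive RBCs. Of 928 Primitive RBCs with mostly embryonic β-globin, 113 held an eGFP UMI (12.2%), as did 1 of 42 with mostly adult β-globin, 3 of 664 such Definitive RBCs and 96 of 253 precursors with mostly embryonic β-globin. The 42 Primitive RBCs with mostly adult β-globin were not set apart from the others: eGFP stood at 19.7 (2.39 to 71.2) in them and at 38.4 in those with embryonic β-globin, at median depths of 1461 and 3274.5 UMIs outside haemoglobin. After thinning to 1000 UMIs outside haemoglobin, the share was 2.64% of Primitive RBCs (1.68 to 3.93; 100 shallower cells left out), 0.389% of Definitive RBCs (0.0472 to 1.40; 151 left out) and 4.72% of precursors (2.46 to 8.11; 0 left out). In Neutrophils, taken as background after the values were seen, it was 0 of 981 cells, with an upper 95% bound of 0.375% (7 left out). Unthinned, the shares were 11.7%, 0.451%, 37.8% and 0.304%, at median depths of 3141.5, 1469, 10764.5 and 3646 UMIs outside haemoglobin. In Decidual stroma the thinned share was 3 of 128 cells, 2.34% (0.486 to 6.70), at 24.5 per 1000000 UMIs outside haemoglobin genes. On the same scale, eGFP stood at 44.1 in SynTI, 43.4 in S-TGC, 44.1 in Macrophage and 29.99 in SpA-TGC, but at 2.87 (0.592 to 8.39) in SynTII and 3.27 (0.0828 to 18.2) in Yolk sac cells, with 0 counts in the 35 Visceral yolk sac and 20 Gly-T cells. In Macrophage, SynTI and SpA-TGC together, chosen after the values were seen, Xist had 1 count in the 55 cells with an eGFP UMI (a level of 1.01) and 1373 in the 461 cells without one (a level of 569), held by 80 of these. Y-linked genes stood there at 63.7 against 23.2 (2.75-fold, 1.89 to 4.01). Over all cells of Macrophage, SynTI and SpA-TGC, Xist stood at 198, 225 and 776 and Y-linked genes at 7.87, 42.9 and 38.8. The mix of types could thus enter both contrasts, and S-TGC was not in this set.

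**Figure D5:**
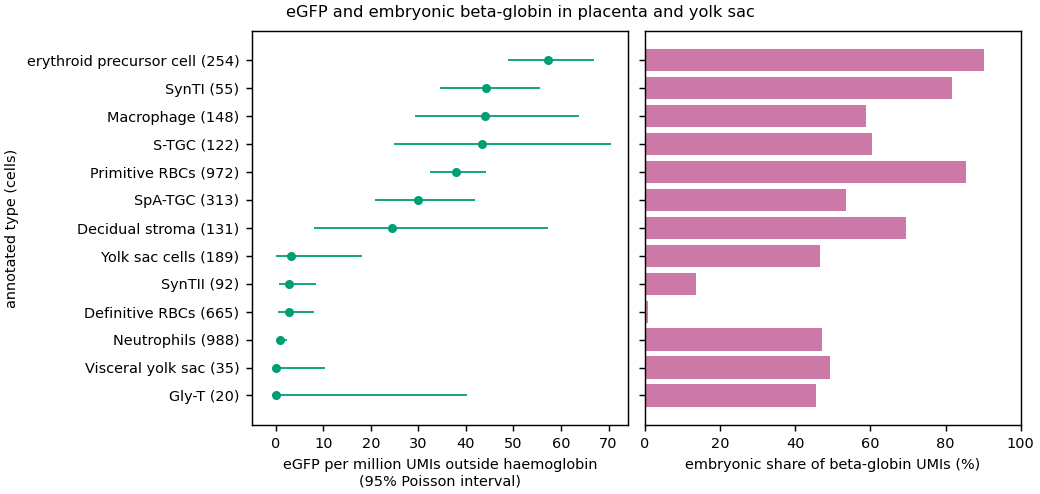
eGFP per 1000000 UMIs outside haemoglobin genes with exact Poisson 95% intervals as error bars, beside the embryonic share of β-globin UMIs in percent (horizontal axes), by type (vertical axis). Precursors stood at 57.3 and 90.2%, Definitive RBCs at 2.72 and 0.855%.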

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

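The tests of depth and of free RNA for eGFP, of the reference for Y-linked reads, and of free RNA and doublets for SynTII and Gly-T were chosen after the result was seen. The others were written down before their values were computed.

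Against the same mTBLC library, of the gene lists apart from random lists in both comparisons, 3 had medians on opposite sides in blastoid and teratoma, and the difference was not tested: primitive endoderm at 2.60 and -1.16, parietal endoderm at 2.19 and -1.15, and neural progenitors and neurons at -2.25 (4 of 5 measured genes lower) and 2.73 (8 of 11 higher), so on partly different members. Without immune cells and fibroblasts and against mTBLC-2MYCP alone, the teratoma medians of primitive endoderm and parietal endoderm were 0.93 and 0.50 and not apart from random lists. In the 4 libraries tied to no time point, zscan4 cells made up 7.88%, 8.58%, 3.52% and 1.94% for barcode suffixes 1 to 4, which no comparison used.

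The first pattern was eGFP in erythroid precursors and Primitive RBCs but hardly in Definitive RBCs. Lower depth in Definitive RBCs did not account for it: after thinning, their upper bound of 1.40% lay under the lower bound of 1.68% in Primitive RBCs. Free RNA reaching all droplets alike was argued against by Neutrophils, of about the depth of Primitive RBCs, whose upper bound of 0.375% lay under the same lower bound, but Decidual stroma held 2.34% (0.486 to 6.70), where free RNA and doublets stay open. A mixture of cells of the eGFP line with other cells could leave Xist only in the latter: among precursors, cells with an eGFP UMI had 0.0758 times the Xist of cells without one (0.0151 to 0.236), an interval that takes UMIs as independent although only 3 of 96 and 6 of 158 cells held any. In the precursors the Y-linked ratio of 1.26 (0.837 to 1.90) included 1, which the rule written beforehand counted as against this explanation. The interval also holds ratios above 1, so the explanation was left open there, a reading that departs from that rule. No explanation from blood development was tested.

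The second pattern was the low level of Y-linked genes in mTBLC-2MYCP, 7.92 CPM (7.44 to 8.43), against 61.4 in the 2D libraries outside feeder cells and 42.7 in the teratoma. The blastoid library stood between these, at 18.4 CPM (15.3 to 22.0). A reference that loses Y-linked reads would lower feeder cells of the same library too, yet these stood 5.51-fold higher (4.47 to 6.73), which argues against it. A culture in which some cells have Y-linked transcripts and others none could give an excess of cells without them: 91.4% of 4465 cells had no Y-linked UMI where 80.2% were predicted by chance, at percentile 99.2 of 1176 genes at a like level. This fits such a mixture and does not show it, since bursts of transcription would leave the same excess. Loss of the chromosome, silencing and another subline were not tested.

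The third pattern was immune genes in the types named SynTII, which they led, and Gly-T, where mast cell and basophil genes were picked after the values were seen and the leading list was immediate early and heat shock (4.55). For SynTII, trophoblast cells with free RNA of immune cells and doublets of both were argued against by Krt8, Krt18 and Epcam at 0.00364 of the level in S-TGC (0.00181 to 0.00652), and for Gly-T, doublets with SynTI or S-TGC cells by the same genes at 0.00793 of that level (0.000959 to 0.0287). First doublet tests used the syncytiotrophoblast and labyrinth list. Against SynTI, SynTII had 0.291 (0.255 to 0.331), above the bound set for it, as doublets would give. This came through Slc16a3, at 179 CPM in SynTII and 208 in Neutrophils. Krt8, Krt18 and Epcam were used instead after these values were seen, so the first and the later test of SynTII disagreed. Gly-T had 0.113 (0.0515 to 0.215) of the level in SynTI, but 0.807 (0.360 to 1.58) of that in S-TGC, which decided nothing. Names that belong to other clusters might account for the pattern. The syncytiotrophoblast median was 3.53 higher in SynTI than in SynTII, which fits but names no cell. SynTI is a syncytiotrophoblast name too, so a higher median there could also arise with right names. No explanation from the biology of the placenta was tested.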

How the results depend on the processing

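The alternatives on doublet scores, on single types and on symbols that met the split rule were chosen after the result was seen. No paired analysis was possible because each group had 1 library and no test was run. The comparison of 2D differentiation at 96 h with 4 h and its 7 alternatives were not run, since the cells were tied to no time point.

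All 6 medians of the totipotency, naive pluripotency and trophectoderm lists kept their sign under every alternative. The reported values were totipotency -2.92, naive pluripotency -2.25, trophectoderm 3.81 for the blastoid and totipotency -4.69, naive pluripotency -2.30, trophectoderm 1.19 for the teratoma comparison, and those that moved were as follows. With totals without mitochondrial, ribosomal protein and haemoglobin genes: blastoid naive pluripotency -2.44, trophectoderm 3.98 and teratoma totipotency -4.50, naive pluripotency -2.53, trophectoderm 0.76. With mean of per-cell CPM: blastoid totipotency -3.32, naive pluripotency -2.54 and teratoma totipotency -4.43, naive pluripotency -2.47. With pseudocount of 5 CPM: blastoid totipotency -2.16, naive pluripotency -2.18, trophectoderm 2.59 and teratoma totipotency -2.66, naive pluripotency -2.04, trophectoderm 0.95. With members measured at 20 CPM: blastoid totipotency -3.57, trophectoderm 4.34 and teratoma totipotency -5.51, naive pluripotency -2.44, trophectoderm 1.92. With cells with at least 1000 genes and at most 10% mitochondrial UMIs: blastoid totipotency -4.07, naive pluripotency -2.12 and teratoma totipotency -3.96. With TMM factors: blastoid naive pluripotency -2.38 and teratoma totipotency -4.80, naive pluripotency -2.49, trophectoderm 1.01. ICM/EPI against mTBLC-2MYCP cells: blastoid totipotency -1.97, naive pluripotency -1.67, trophectoderm 1.76. Without immune cells and fibroblasts against mTBLC-2MYCP cells: teratoma naive pluripotency -2.38, trophectoderm 1.75. Members without symbols that met the split rule: teratoma totipotency -4.45. The teratoma trophectoderm list was no longer apart from random lists with members from 20 CPM. Between ICM/EPI and mTBLC-2MYCP cells the median of immediate early and heat shock turned from 0.88 to -0.18. Against mTBLC-2MYCP without immune cells and fibroblasts, primitive endoderm turned to 0.93 and parietal endoderm to 0.50. Under the cell filter the share of mTBLC-2MYCP was 89.2% and that of Neutrophils 38.0%; it kept 2427 mTBLC and 1681 placenta and yolk sac cells. Of 517 alternative values of list medians, 495 kept the call, 15 lost and 7 gained it, and none of 512 values of named genes changed sign. The mean of per-cell CPM gave 0.576 (Krt5 in SynTI) to 2.38 (Gzmd in Decidual stroma) times the reported marker levels by type; Prl3b1 in SpA-TGC was at 1876 in place of 913 CPM. A larger pseudocount shrinks ratios by construction; for the other moved values the cause was not tested.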

Other observations

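The per-library shares of the pooled table and the Xist levels by type were chosen after the result was seen, while the gene lists were fixed before.

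Targets of p53, the factor of the DNA damage response, were lower in the teratoma than in the mTBLC culture: 8 of 15 measured genes were at least 2-fold lower and 0 higher (median -1.16, counting interval -1.30 to -1.05). Cdkn1a, a cell cycle inhibitor gene, stood at 46.3 against 274 CPM, Phlda3 at 25.5 against 126 and Perp at 2.20 against 43.7. In the blastoid library the same list was not apart from random lists (-0.20). Genes of glycolysis were higher in the teratoma (8 of 13, median 1.51), with lactate dehydrogenase (Ldha) at 1759 against 470.1, Pgk1 at 937 against 231 and the glucose transporter gene Slc2a1 at 411 against 87.9 CPM, and higher in the blastoid too (5 of 13, median 0.60). Immediate early and heat shock genes, which also respond to cell dissociation, were higher in 7 of 10 (median 1.58), with Fos at 448 against 15.5 and Egr1 at 318 against 30.3 CPM, and in the blastoid in 3 of 9 (median 0.88). That blastoid median was not apart from random lists with members from 20 CPM (0.45, percentile 86.2) and was -0.18 between ICM/EPI and mTBLC-2MYCP cells. Imprinted genes were higher in the teratoma as well (9 of 12, median 2.27), with Mest at 444 against 29.2 and Peg3 at 421 against 14.3.

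The DNA methylation enzymes as a list were not apart from random lists in either comparison (-0.10 and 0.19), yet single members lay on opposite sides. The de novo enzyme gene Dnmt3a stood at 33.2 against 8.87 CPM in blastoid against mTBLC culture and at 85.4 against 8.87 in teratoma against mTBLC culture, while the demethylation gene Tet1 stood at 59.98 against 218 and 92.9 against 218, and Zfp57, which guards imprints, at 17.8 against 157 and 21.1 against 157. G1/S genes were higher in the teratoma (median 0.70, with 2 of 12 at least 2-fold, and not apart from random lists with the mean of per-cell CPM, percentile 96.4) and G2/M genes not apart (0.27). The spliceosome list was not apart in either comparison (-0.02 and 0.19). In placenta and yolk sac, erythroid precursors had 11 of 12 measured G2/M genes higher than all other cells (median 3.15).

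In the 4 libraries tied to no time point, major_zga made up 72.2% of the cells with barcode suffix 1, cell4 73.2% with suffix 2, cell8_16_morula 80.6% with suffix 3, and post-epi 46.1%, epi 34.3% and xen 14.3% with suffix 4. Feeder cells made up 14.3%, 9.28%, 0.541% and 0.857%, and TE 2.26%, 2.64%, 4.66% and 1.21%. Of all cells of their type, 94.0% of major_zga, 88.1% of cell4 and 95.2% of cell8_16_morula came from 1 library each. Those of post-epi, epi and xen came mostly from 1 library, that of suffix 4 (99.8%, 96.7% and 90.8%). Types were not compared within libraries. In XEN-like cells of the mTBLC culture Xist stood at 96.01 CPM, against 3.68 in mTBLC-2MYCP and 310.0 in feeder cells, and in TE cells of the blastoid at 69.5 against 6.57 in ICM/EPI.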
